A study of Mus musculus with 7 samples.

How the data were processed

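RNA sequencing measured transcript levels in 7 mouse libraries. One library came from mouse embryonic fibroblasts (MEFs) and one from control neural stem cells (cNSCs) taken from embryonic cerebral cortex. The other 5 came from induced neural stem cells (iNSCs), which are fibroblasts converted with viral reprogramming factors and neural stem cell medium. Per the labels' protocols, RNA from 2 to 3 biological replicates was pooled before each library was made, so the deposited values hold no spread within a line. The only group with more than 1 library was mcBKSM, with clones numbered 1 and 3.

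The deposited table gave FPKM (fragments per kilobase of transcript, scaled to library size) for 24354 gene symbols. Per the submitters' processing notes, STAR 2.5.2b, Cufflinks 2.2.1, Cuffnorm and R 3.3.2 were used with genome build mm10; the role of each tool and the settings are not given in the sources used here. FPKM corrects for transcript length and for library size, and Cuffnorm scales libraries against each other, so a change in total RNA per cell cannot be seen in these values. All 7 columns matched a sample title.

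The files hold no counts. Depth was estimated from low values of genes with 1 annotated transcript, because the value of 1 fragment sets the step between them. As a separate check that low values move in steps, libraries were set to a common scale. Each low value was then divided by the same gene's smallest nonzero value. Of 13462 low values, 49.9% lay within 0.03 of a whole multiple, where 6.0% would do so by chance. This check did not use the depth estimates. In units of 1e6 fragments, the estimates were 15.2 for MEF, 15.2 for cNSC, 11.9 for pOKSM, 10.7 for pBKSM, 13.7 for mcBKSM clone 1, 12.8 for mcBKSM clone 3 and 16.3 for the DTA line. They are approximate, since many low values were not whole multiples. At these depths 3 fragments on a transcript of 2 kb correspond to 0.0921 FPKM in the DTA library and 0.14 FPKM in the pBKSM library, and values near or below this are at the floor. This floor covers counting error only. An FPKM of exactly 0 is reported as listed at 0.

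FPKM values were used as log2(FPKM + 1). Genes with at least 1 FPKM in at least 1 library of a fit were tested with limma-trend (limma 3.58.1, R 4.3.3) and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All differences are on the log2(FPKM + 1) scale, which understates changes of low genes. The 3 classes (iNSC, MEF, cNSC) in 1 fit served the class comparisons, with 4 residual degrees of freedom from the 5 iNSC libraries. Of these, pOKSM and the 2 mcBKSM clones were close, with 1.26% to 2.81% of genes 2-fold or more apart. SDs, SEs and p-values over the 5 libraries treat them as independent all the same. The 6 label groups in 1 fit served pBKSM against mcBKSM and against pOKSM, with 1 residual degree of freedom from the 2 mcBKSM clones. The polycistronic lines and the DTA line were compared in fits of the 4 and 5 libraries concerned. In each fit a group with a lone library was assumed to vary like the replicated side. The p-values therefore measure spread between lines or between clones, which are not repeats of one line.

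Gene groups were described with 30 lists of cell type markers, pathways and gene classes, written before the data were examined, as were the tests and the rule for naming genes. Lists with at least 5 tested members were tested in the class comparisons with camera (limma), with a preset correlation of 0.01 and, as an alternative, an estimated correlation. Counts adjusted over the list alone are given beside counts over all genes tested. For pBKSM against mcBKSM, each list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Reference sets were genes that differed 4-fold or more between cNSC and MEF on the log2(FPKM + 1) scale with at least 5 FPKM in the higher library.

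Named genes followed a fixed rule. Part (a) took the 5 reprogramming factor genes and Nes, Pax6, Olig2, Sox1, Col1a1, Thy1 and Nanog. Results on an item withheld for evaluation are left out. Part (b) took, of each list described, up to 4 called members with the largest differences, or up to 2 as values where none was called. Part (c) took the 5 largest rises and 5 largest falls among called genes whose libraries did not overlap between the sides. Where fewer than 20 genes were called or no test was run, part (c) took the 5 largest differences each way with at least 5 FPKM in the higher side, as values. Part (c) skipped names starting with Gm or Mir or ending in Rik, snoRNA genes and ribosomal protein genes. Genes named outside this rule are said to be so.

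The tests were checked on simulated tables with 50 genes changed at each of 4 fold changes, drawn from the real means and spreads. The changed genes were taken from the more highly expressed genes only, so recovery of low genes is not known. In the comparison of iNSC lines with MEFs (13042 genes), 8% of genes changed 2-fold, 52% changed 4-fold and 86% changed 8-fold were recovered. For pBKSM against mcBKSM (13042 genes) these shares were 38%, 96% and 98%. Calls among unchanged simulated genes were 0.0389% and 0.164% in these 2 comparisons. Each gene had the same simulated spread in every library, and libraries were drawn independently. The simulated shares therefore hold only if a lone library varies like the replicated side and the lines are independent. Neither condition was checked by the simulation. Of genes changed 2-fold, 4% were recovered for iNSC lines against cNSCs and 2% for DTA against the other lines. Camera called 50 of 50 simulated lists of 20 genes shifted by 1 on the log2 scale and 0 of 50 unshifted lists. The simulated genes varied independently, so this gives no error rate for lists of correlated genes. Estimated correlations in the real lists ran from -0.0817 (oligodendrocyte lineage) to 0.517 (cholesterol genes).

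Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization, leaving out each library of a replicated side, a fit of the 3 BKSM libraries alone, and the DTA line against the mcBKSM clones alone. Removal of a transcript length trend, list tests without each line, and the contrasts pOKSM against mcBKSM and DTA against cNSC were added after seeing the data. Transcript lengths came from an annotation of the same assembly and were known for 95.7% of symbols. Figures and closing tests used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.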

Results

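The series holds 7 libraries, which were compared: 1 of MEFs, 1 of cNSCs and 5 of iNSCs. The iNSC libraries were pOKSM, pBKSM, mcBKSM clone 1, mcBKSM clone 3 and a DTA line. The growth protocol names polycistronic vectors, which carry several factors on 1 transcript, and monocistronic vectors, which carry 1 factor each, and the prefixes p and mc are read here as these. K, S and M stand for Klf4, Sox2 and Myc, O for Oct4 (gene Pou5f1) and B for Brn4 (gene Pou3f4). The DTA line came from fibroblasts in which Oct4-CreER is combined with a Cre-dependent diphtheria toxin gene, so that cells activating Oct4 under induction are killed. Its vector is not given in the labels. Between 10907 genes (MEF) and 11429 genes (cNSC) reached 1 FPKM. Groups other than mcBKSM had 1 library, so their values carry no replicate error.

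The factor genes were examined first. Pou5f1 was listed at 0 in MEF, cNSC, pBKSM and DTA, and was 0.202 FPKM in pOKSM, 0.398 in mcBKSM clone 1 and 0.187 in clone 3, close to the detection floor. Pou3f4 was 19.99 FPKM in pBKSM, 24.1 in DTA, 27.2 in cNSC and 2.26 in pOKSM, and was listed at 0 in both mcBKSM clones. Sox2 was 277 FPKM in pOKSM and 342 and 390 in the mcBKSM clones, against 87.6 in pBKSM, 106 in DTA and 107 in cNSC. Myc was 339 FPKM in pOKSM and 450 and 485 in the clones, against 78.9 in pBKSM, 50.1 in DTA, 42.5 in cNSC and 47.8 in MEF. Klf4 ranged from 4.08 FPKM (cNSC) to 21.8 FPKM (MEF). FPKM per gene does not part vector from endogenous transcripts, and Pou5f1 near the floor does not check the pOKSM label. Pou3f4 listed at 0 in both clones shows no transcript of this gene at sampling, which leaves the B in the label mcBKSM unchecked. That label is used below as a name only. Nanog stayed at or under 0.480 FPKM in each library.

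To see how far each line resembled the reference cells, libraries were compared in pairs. Among genes with at least 5 FPKM in either library, the mcBKSM clones differed 2-fold or more at 114 genes (1.26%). The pOKSM library was nearly as close to them, with 255 genes (clone 1) and 205 genes (clone 3), while pOKSM and pBKSM differed at 1074 genes. The DTA line differed from cNSC at 981 genes and from pBKSM at 988. MEF differed from each other library at 2923 to 3355 genes.

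**Figure D1:**
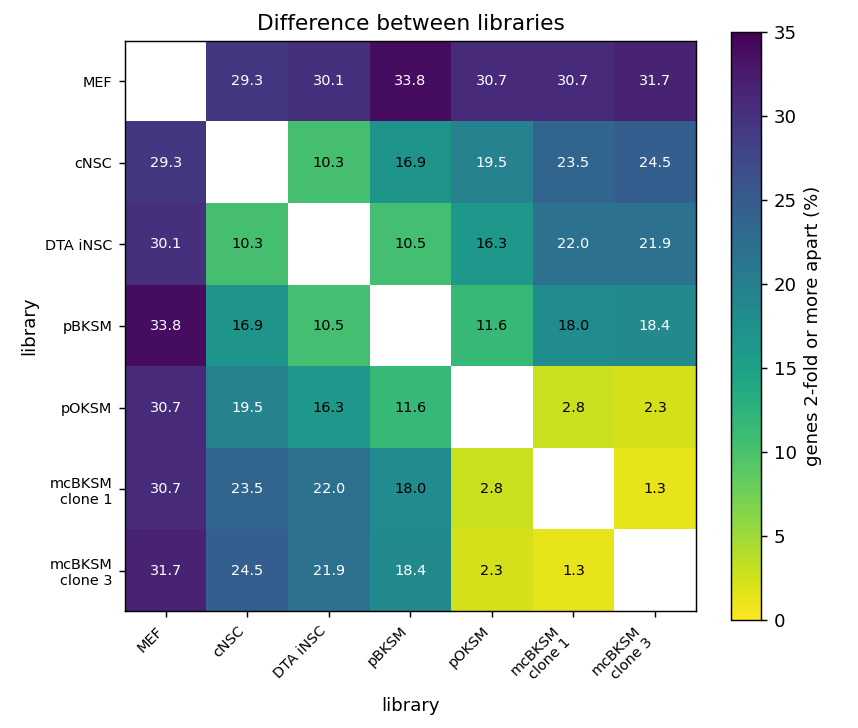
Percentage of genes that differ 2-fold or more on the log2(FPKM + 1) scale between each pair of the 7 libraries, among genes with at least 5 FPKM in either library; both axes list the libraries. pOKSM lies within 2.81% of both mcBKSM clones, which differ from each other at 1.26%.

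The cortical and fibroblast libraries differed 4-fold or more at 1399 genes, of which 753 were higher in cNSC (NSC-high) and 646 higher in MEF (MEF-high). The largest NSC-high differences were Ckb (brain creatine kinase, 5593 FPKM in cNSC against 0.468 in MEF), Fabp7 (a radial glia lipid carrier, 1654 against 0), Igfbp2 (882 against 0), Igfbp3 (822 against 0) and Olig1 (393 against 0). The largest MEF-high differences were the collagen genes Col1a2 (462 FPKM in MEF, listed at 0 in cNSC) and Col1a1 (440 against 0.242), Cd34 (334 against 0.0532), Bgn (331 against 0.0550) and Il1rl1 (305 against 0.0446). Of the lists, 21 of 28 neural stem cell genes and 9 of 15 astrocyte genes were NSC-high, and 27 of 33 fibroblast genes were MEF-high. This comparison of 2 libraries has no replicate check, and strain differed between them as well.

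Each iNSC line was then placed between these references by counting genes beyond the cNSC and MEF midpoint. NSC-high genes lay on the cNSC side for 82.2% in DTA, 78.4% in pBKSM, 69.9% in pOKSM, 59.6% in mcBKSM clone 1 and 56.0% in clone 3 (mean 69.2% ± 11.4, SD, n = 5). MEF-high genes lay on the cNSC side for 91.8%, 92.1%, 82.0%, 76.3% and 78.5% in the same order (mean 84.1% ± 7.41, SD, n = 5). Of the NSC-high genes, 356 lay on the cNSC side in all 5 lines and 73 in none. Of the MEF-high genes, 444 did so in all 5 lines and 13 in none. These shares are descriptions without a test.

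Against MEFs, the iNSC lines gained neural stem cell transcripts and lost fibroblast transcripts. In the neural stem cell list, 14 of 28 tested genes rose and 0 fell (18 rose adjusted over the list alone). Nes, encoding the intermediate filament nestin (chromosome 3, 87971093 to 87980451, mm10), was 189 ± 56.4 FPKM in the lines (SD, n = 5) and 0.103 in MEF, a log2 difference of 7.38 ± 0.40 (SE, adjusted p = 0.000231). Fabp7 (2065 ± 1893 FPKM), Sox2 (240 ± 137), Olig2 (178 ± 148), Bcan (224 ± 137) and Pax6 (8.28 ± 2.73) also rose and were listed at 0 in MEF. Sox1, at 18.6 ± 12.3 FPKM in the lines and listed at 0 in MEF, did not pass (adjusted p = 0.104). Camera gave the list an adjusted p of 7.4e-09, and adjusted p = 0.148 with an estimated correlation.

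Of 31 tested fibroblast genes, 23 fell and 0 rose (24 fell adjusted over the list alone). Col1a1, encoding a chain of type I collagen (chromosome 11, 94936224 to 94953042, mm10), was 440 FPKM in MEF and 0.377 ± 0.340 in the lines, a log2 difference of -8.35 ± 0.34 (SE, adjusted p = 9.3e-05). S100a4 (3002 FPKM in MEF, 3.37 ± 2.70 in the lines), Col1a2 (462, 0.0191 ± 0.0357), Dcn (144, 0.0423 ± 0.0435) and Thy1 (111, 0.252 ± 0.339) fell as well. This was the only list that camera called with either correlation (adjusted p = 2.0e-17, and adjusted p = 0.0281 with an estimated correlation).

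Signalling and metabolic lists moved too. In the interferon list 14 of 22 genes fell and 0 rose (17 fell adjusted over the list alone), among them the antiviral genes Isg15 (63.1 FPKM in MEF, 2.19 ± 1.46 in the lines) and Ifit1 (17.8, 0.202 ± 0.174). In the TGF-beta and BMP list 9 of 21 fell and 2 rose (10 and 4 adjusted over the list alone), with the BMP antagonist Grem1 falling from 125 FPKM to 0.00914 ± 0.0204. In the cholesterol list 7 of 17 rose and 0 fell (12 rose adjusted over the list alone), including Insig1 (6.14 FPKM in MEF, 68.7 ± 14.7 in the lines) and the reductase gene Dhcr7 (6.17, 51.5 ± 5.22). In the Notch list 4 of 13 rose and 0 fell (4 adjusted over the list alone), including the targets Hey1 (0.0902, 75.1 ± 48.6) and Hes1 (3.49, 33.3 ± 6.74). Camera called these lists (adjusted p = 3.8e-09, 0.0205, 1.3e-05 and 0.00313 in the order given), and adjusted p was 0.287, 0.24, 0.396 and 0.24 with an estimated correlation.

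Camera called 5 further lists. Astrocyte genes gave 3 of 14 higher and 0 lower, with Aldoc, a glycolytic enzyme gene, at 235 ± 170 FPKM against 0.244. Paternally expressed imprinted genes gave 6 of 22 higher and 1 lower: Peg10 (60.8 ± 23.3 FPKM) and Sgce (35.05 ± 6.23) rose from 0 in MEF, and Dlk1 fell from 131 FPKM to 0.290 ± 0.470. Antigen presentation genes gave 2 of 8 lower (B2m, 627 FPKM in MEF and 197 ± 36.9 in the lines), glycolysis genes 2 of 16 lower (Slc2a1, the glucose transporter gene, 87.7 and 20.3 ± 4.13) and proliferation genes 3 of 26 lower (Mcm5, 161 and 65.1 ± 10.1). Adjusted over the list alone, the counts were 3 higher and 1 lower, 8 higher and 1 lower, 2 lower, 2 lower and 1 lower. Camera adjusted p was 0.0336, 0.0336, 0.0243, 0.0146 and 0.0277, and adjusted p was 0.489, 0.396, 0.324, 0.489 and 0.396 with an estimated correlation. With other processing settings, calls ended for astrocyte (adjusted p = 0.0644) and proliferation genes (0.0952) with quantile normalization, for paternally expressed imprinted (0.0769) and proliferation genes (0.0545) without a filter, and for TGF-beta and BMP genes (0.0503) with a pseudocount of 0.1. In list tests added after seeing the data, the proliferation and the TGF-beta and BMP calls ended without DTA (adjusted p = 0.0571 and 0.0567).

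In all, limma called 2128 of 13042 genes, 883 higher and 1245 lower in iNSCs. The largest rises were Ckb (log2 difference 11.39 ± 0.57, SE), Fabp7 (10.48 ± 1.34), Igfbp2 (9.57 ± 0.77), Olig1 (8.37 ± 1.69) and Sox2 (7.67 ± 0.93). The largest falls were S100a4 (-9.69 ± 0.97), the related calcium-binding gene S100a6 (-9.67 ± 1.12), Col1a2 (-8.83 ± 0.16), Col1a1 and the matrix proteoglycan gene Bgn (-8.30 ± 0.17). Klf4, Myc and Pou3f4 did not pass (adjusted p = 0.221, 0.375 and 0.517). The test sets 1 MEF library against spread between lines, and leaving out pOKSM gave 1147 genes while leaving out DTA gave 3193. Without mcBKSM clone 3 the count was 1417.

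**Figure D2:**
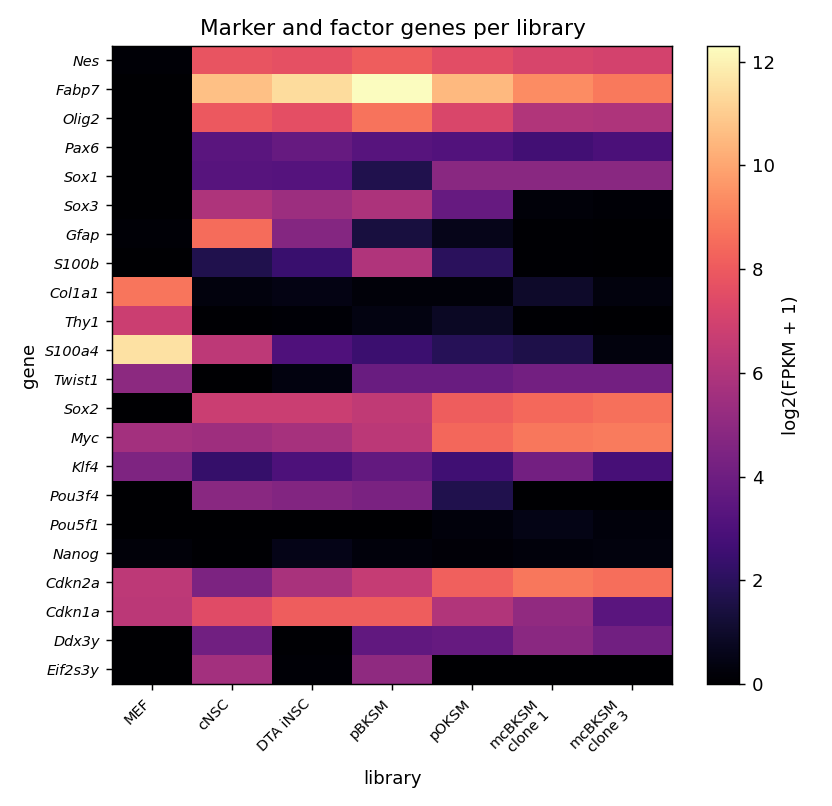
Heat map of log2(FPKM + 1) for 22 marker and factor genes (y axis) in the 7 libraries (x axis), 1 library per column. Nes is near 0 in MEF and between 132 and 275 FPKM in the other 6 libraries, while Col1a1 is 440 FPKM in MEF and under 1 FPKM in the others.

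Against cNSCs, fewer genes differed. Genes higher in cNSC included Vgf, encoding a secreted neuropeptide precursor (199 FPKM against 0.172 ± 0.154 in the lines, SD, n = 5; log2 difference -7.42 ± 0.23, SE, adjusted p = 0.000269), Col6a1 (221 against 1.06 ± 0.981), Col6a2 (158 against 0.522 ± 0.355), Eno1b (91.5 against 0.160 ± 0.176) and Calca (60.1 against 0.112 ± 0.111). Eno1b is a near copy of Eno1, so its value is uncertain. Genes higher in iNSCs included Pdpn (50.6 ± 18.2 FPKM against 3.69), Lmcd1 (18.1 ± 3.60 against 1.21), Tle2 (38.4 ± 7.12 against 5.004), Sirpa (42.3 ± 4.37 against 6.04) and Pde1c (11.9 ± 1.76 against 1.27). Nes, Pax6, Olig2, Sox1 and Sox2 did not pass (smallest adjusted p = 0.667, Sox2).

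Of the lists, fibroblast genes gave 6 of 31 lower in iNSCs and 0 higher (7 lower and 1 higher adjusted over the list alone), with Acta2 (47.5 FPKM in cNSC, 0.229 ± 0.354 in the lines) beside Col6a1 and Col6a2. Camera did not call this list (adjusted p = 0.366). Camera called 7 lists, in which 1 member was called: the mitosis gene Birc5 of the proliferation list (1 of 26, 10 adjusted over the list alone) rose from 50.1 FPKM in cNSC to 124 ± 10.7 in the lines. Proliferation (adjusted p = 0.000176), Hox and Hedgehog genes (0.0374 each) were called higher in iNSCs. Cholesterol (0.000302), interferon (0.000329), astrocyte, and midbrain and hindbrain genes (0.0374 each) were called lower, with 0 members called in each of these 6 lists. The astrocyte filament gene Gfap was 374 FPKM in cNSC and 5.35 ± 10.7 in the lines, without passing (adjusted p = 0.19). All 7 list calls were lost with an estimated correlation (adjusted p = 0.732 for each). With other processing settings, calls ended for Hox (adjusted p = 0.0653) and Hedgehog genes (0.0575) with quantile normalization, and for midbrain and hindbrain genes (0.0529) with a pseudocount of 0.1. Without a filter, they ended for astrocyte (0.163), midbrain and hindbrain (0.662) and Hedgehog genes (0.22). In list tests added after seeing the data, the Hox and Hedgehog calls ended without DTA (adjusted p = 0.256 and 0.214), and the astrocyte and midbrain and hindbrain calls ended without mcBKSM clone 3 (0.0706 and 0.0505).

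Limma called 152 of 13042 genes, 27 higher and 125 lower in iNSCs. Leaving out pOKSM gave 50 genes, mcBKSM clone 3 gave 59, mcBKSM clone 1 gave 70, and leaving out DTA gave 883 with 353 higher. Strain differed between cNSC and the other libraries, so differences between iNSCs and cNSC cannot be told apart from a strain effect. A contrast of the DTA line alone with cNSC, added after seeing the data, set 1 library against 1. Its spread came from the 2 mcBKSM clones, so its count does not compare with that of the class comparison. Its calls were lost after quantile normalization. By pairs of libraries, DTA was the iNSC line closest to cNSC, with 10.3% of genes 2-fold or more apart.

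By label, pBKSM and the clones labelled mcBKSM share their factors and differ in vector type, but Pou3f4 was not seen in the clones, so a difference in factors is not excluded. In pBKSM, the astrocyte gene S100b (chromosome 10, 76253836 to 76261319, mm10; 61.5 FPKM against 0.0450 in clone 1 and 0 in clone 3), Spon1 (83.6 against 0.134 and 0), Atp6v0e2 (73.4 against 0.0807 and 0.0444), Cmtm5 (54.3 against 0.0935 and 0) and the neural progenitor regulator Sox3 (58.8 against 0.177 and 0.0779) were higher. Olig2 was higher at 423 FPKM against 65.1 and 59.5 (log2 difference 2.75 ± 0.10, SE, adjusted p = 0.0367), and Pou3f4 was higher as well. The clones had more Mab21l2 (87.7 and 85.3 FPKM, listed at 0 in pBKSM), Moxd1 (89.3 and 98.9 against 0.148), Ifitm3 (382 and 335 against 3.45), Bst2 (117 and 104 against 0.436) and Lxn (75.6 and 76.8 against 0.0937). They also had more Sox2 (log2 difference, pBKSM minus clones, -2.05 ± 0.13, adjusted p = 0.0471), Myc (-2.55 ± 0.10, 0.0373) and Sox1 (-3.10 ± 0.13, 0.0374), while Nes did not pass (adjusted p = 0.0647).

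Astrocyte genes were higher in pBKSM for 5 of 14 members and lower for 0 (8 and 2 adjusted over the list alone), and neural stem cell genes for 5 of 28 with 2 lower (12 and 8 adjusted over the list alone). Neuronal genes were lower for 3 of 17 and higher for 2 (10 and 3 adjusted over the list alone), with the neuronal splicing factor gene Rbfox3 at 1.62 FPKM against 29.7 and 26.0. Hox genes were lower for 4 of 30 and higher for 0 (11 and 1 adjusted over the list alone), with Hoxb3 listed at 0 in pBKSM and at 17.1 and 22.7 FPKM in the clones. Medians of 9 lists lay outside the central range of random lists set beforehand, as a description of these libraries. Neural stem cell, astrocyte, midbrain and hindbrain, p53 target, Wnt, glycolysis and cholesterol genes lay above (percentiles from 99.92 to 100), and neuronal (0) and interferon (0.13) genes below. Of the p53 list only Bax was called (310 FPKM against 115 and 105), with 10 higher and 4 lower adjusted over the list alone.

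Limma called 759 of 13042 genes, 488 higher and 271 lower in pBKSM. The spread came from 1 residual degree of freedom and the smallest adjusted p was 0.0367, so the count is sensitive to the fit: 2536 genes were called from the 3 BKSM libraries alone and 1454 with a 5 FPKM filter.

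By label, pBKSM and pOKSM differ by B in place of O in the polycistronic vector, but Pou5f1 near the floor in pOKSM leaves the O unchecked. This comparison gave 0 called genes by limma (3269 at an unadjusted p under 0.05, smallest adjusted p = 0.102). The largest values in pBKSM against pOKSM were Tex13 (32.3 FPKM, listed at 0 in pOKSM), Eif2s3y (31.2, listed at 0), Chl1 (29.5 against 0.492), S100b (61.5 against 2.99) and Pcdhgb7 (13.9 against 0.474). In the other direction were Moxd1 (89.1 FPKM in pOKSM), Lxn (84.3), Ifitm3 (287), Mab21l2 (59.3) and Crip1 (45.4, listed at 0 in pBKSM). Both sides had 1 library, so spread was borrowed from the mcBKSM clones. Counts rose to 374 without a filter and 90 with a 5 FPKM filter.

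Both polycistronic lines against both clones labelled mcBKSM gave 2 called genes of 12091 (1014 at an unadjusted p under 0.05). Both were lower in the polycistronic lines: Eif3j1, a translation initiation factor gene with a near-identical copy (0.112 and 0.121 FPKM against 26.9 and 26.3), and the small nucleolar RNA gene Snora65, which the naming rule skips and which was named after its value was seen. The copy, Eif3j2, also named after its value was seen, was 27.4 and 22.6 FPKM in pOKSM and pBKSM against 1.66 and 0.654 in the clones, so reads shared between the copies make both values uncertain. Without pOKSM the count was 2536, and without either clone it was 0. As values, the polycistronic lines (pOKSM, then pBKSM) had more Spon1 (16.7 and 83.6 FPKM), Acot1 (18.2 and 72.7), Apln (38.5 and 72.5), Atp6v0e2 (14.2 and 73.4) and Sox3 (12.9 and 58.8), each at most 1.16 in the clones. The clones had more Bst2 (117 and 104 FPKM), Cxcl10 (45.3 and 57.1), Mab21l2 (87.7 and 85.3) and Crip1 (64.1 and 73.2), and pOKSM held 51.5, 16.5, 59.3 and 45.4 FPKM of these. In a contrast added after seeing the data, pOKSM against the clones gave 0 called genes (1119 at an unadjusted p under 0.05).

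The DTA line, from the genotype with the toxin gene, was set against the other 4 iNSC lines. Its library also differed in composition, with Malat1 at 153 FPKM against 29.0 to 53.5 in the other lines. Ribosomal protein genes took 13.3% of summed FPKM against 20.8% to 24.7%. How far this composition moves the calls below was not tested. Of 29 tested Hox genes, 7 were higher in DTA and 0 lower (12 and 1 adjusted over the list alone). The Hoxd cluster did not follow in all lines: DTA had 3 Hoxd genes at 1 FPKM or more. This compares with 6 in pOKSM and in each clone, and 0 in pBKSM. Hoxa9 (chromosome 6, 52223097 to 52227370, mm10) was 26.6 FPKM in DTA and at most 0.165 in the other lines (log2 difference 4.72 ± 0.23, SE, adjusted p = 0.0109), and Hoxc6 (20.2), Hoxc8 (19.04) and Hoxb6 (18.2) were higher as well. Nell2 (232 FPKM against 7.58 to 12.1), the neural tube regulator Dbx2 (43.9 against at most 0.734) and the water channel gene Aqp4 (12.7 against at most 0.560) were also higher. Mest, a paternally expressed imprinted gene (chromosome 6, 30733506 to 30748466, mm10), was 0.0263 FPKM in DTA and 233 to 340 in the other lines (log2 difference -8.09 ± 0.23, adjusted p = 0.00269). Of 18 tested fibroblast genes 2 were lower and 0 higher (2 lower and 3 higher adjusted over the list alone). These genes, Mmp2 (0.732 FPKM against 29.0 to 45.2) and Twist1 (0.280 against 13.4 to 16.9), were lower, as were Fam111a (0.0963 against 18.5 to 32.2) and the RNase P RNA Rpph1 (4.19 against 50.5 to 81.7).

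Limma called 44 of 12378 genes, 25 higher and 19 lower in DTA. The balance depended on processing. Most calls were lower in DTA with a pseudocount of 0.1 or a 5 FPKM filter. Most were higher without a filter, with quantile normalization and with the length trend removed. Of 4 tested blood and microglia genes 1 was higher and 0 lower (2 higher adjusted over the list alone): the macrophage marker Lyz2 (16.1 FPKM, listed at 0 in the other lines, 44.0 in MEF). Astrocyte genes gave 1 of 14 higher (Aqp4) and 0 lower (5 and 1 adjusted over the list alone). The count was 0 without mcBKSM clone 1, 2 without clone 3, 3 without pOKSM and 3951 without pBKSM. Against the 2 clones alone it was 1455.

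**Figure D3:**
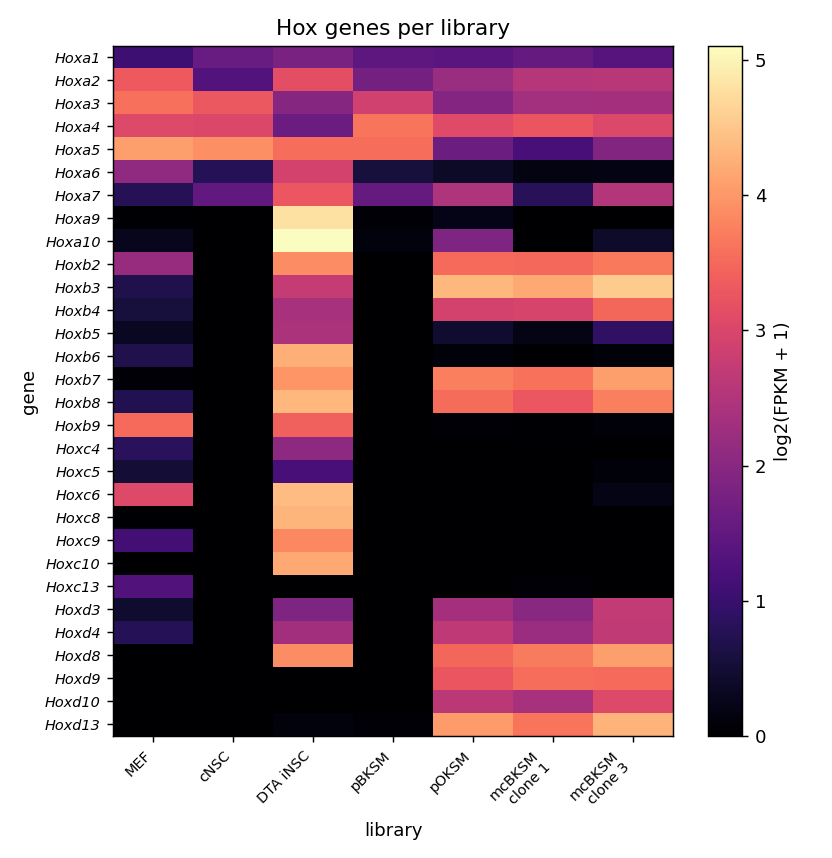
Heat map of log2(FPKM + 1) for the Hox genes with at least 1 FPKM in any library (y axis) in the 7 libraries (x axis). At 1 FPKM or more, cNSC and pBKSM have 6 of 39 Hox genes, all from the Hoxa cluster, and DTA has 26 from 4 clusters.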

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

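Among the 5 iNSC lines, 32 list means, shares and library measures were searched for a line far from the others, and 3 stood out where chance would give about 1.6. The test of library composition was written before its result was seen, and the means without 1 gene were chosen after the results were seen.

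The mean log2(FPKM + 1) of germline genes silenced by DNA methylation was 0.565 in pBKSM and 0.289 to 0.324 in the other lines, and Tex13 (32.3 FPKM in pBKSM, listed at 0 elsewhere) carries most of this: without it, a value added after seeing the data, the mean was 0.361 in pBKSM and 0.302 to 0.339 in the other lines. The mean of neural crest genes was 0.824 in DTA and 0.577 to 0.639 in the other lines. It rests on Tfap2a (4.58 FPKM in DTA): without this gene, also added after seeing the data, the mean was 0.686 in DTA and 0.622 to 0.692 in the other lines. Malat1, a nuclear RNA, was 153 FPKM in DTA and 29.0 to 53.5 in the other lines.

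The cNSC library had a similar Malat1 level (178 FPKM), and DTA and cNSC were alike in composition: ribosomal protein genes took 13.3% and 12.5% of summed FPKM, against 16.4% in MEF and 20.8% to 24.7% in the other lines. DTA and cNSC also differed at fewer genes (10.3% 2-fold or more) than pBKSM and cNSC (16.9%). The prediction was that removing ribosomal protein content and a transcript length trend would close this gap if they were its whole cause. A gap of 5.23 percentage points (SE 0.495 over genes, which are not independent) was left of 6.64. After removal, the share of genes 2-fold or more apart from cNSC was 10.3% in DTA and 15.5% in pBKSM. For the genes compared, this argues against the 2 features, as measured here, as the whole cause of the gap. Both were small beside a 2-fold limit. Only 78 ribosomal protein genes were counted, while 9508 genes were compared between cNSC and pBKSM. Median log2 deviations of the shortest transcripts were small: -0.114 in cNSC, -0.114 in DTA and 0.123 in pBKSM. As a cause of part of the gap, these 2 features stay open. Other differences in library preparation may act gene by gene and stay open too, as does a shared cell state, which was not tested.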

How the results depend on the processing

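No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. For iNSCs against MEFs, counts stayed within 1.5 times of 2128 with another pseudocount, filter or scaling, but the share of higher calls (41.5%) was 52.6% with a pseudocount of 0.1 and 29.9% without a filter; leave-one-out counts ran from 1147 to 3193. For iNSCs against cNSCs (152), a pseudocount of 0.1 and a 5 FPKM filter each gave 74, no filter gave 618, and leave-one-out counts ran from 50 to 883. For pBKSM against mcBKSM (759, 64.3% higher), a 5 FPKM filter gave 1454, the 3 BKSM libraries alone 2536, and removal of the length trend 2679 (53.1% higher); no filter gave 781 (86.7% higher), sharing 309 genes with the 759. For pBKSM against pOKSM (0), a pseudocount of 0.1 gave 7, no filter 374, a 5 FPKM filter 90 and removal of the length trend 192. Polycistronic lines against mcBKSM (2) gave 0 with a pseudocount of 0.1, without a filter and with a 5 FPKM filter, and leave-one-out counts from 0 to 2536. For DTA against the other lines (44, 56.8% higher), a pseudocount of 0.1 gave 17 (17.6% higher), no filter 583 (79.8%), a 5 FPKM filter 16 (18.8%), the mcBKSM clones alone 1455, and leave-one-out counts 0 to 3951. The cause of these moves was not tested. Leave-one-out fits hold fewer samples, and their spread also comes from other libraries. Without pBKSM, the DTA fit takes its spread from pOKSM and the 2 mcBKSM clones, where only 1.26% to 2.81% of genes were 2-fold or more apart. The polycistronic fit without pOKSM is the same fit as that of the 3 BKSM libraries alone, so they are 1 result. Leaving out a clone in the fit with 6 groups leaves no residual degrees of freedom, so no such count exists. With an estimated correlation, list calls went from 11 to 1 (MEF) and from 7 to 0 (cNSC); no filter gave 4 for cNSC. The 4-fold counts, the shares per line and the 9 lists outside random lists moved less than the limits set. Of the named genes' alternative values, 851 kept direction and side of the threshold, 71 lost the call, 60 gained one and 7 reversed, none of those 7 called: Col1a1 log2 difference against cNSC (leave-one-out -0.0173 to 0.17, and -0.19 with the length trend removed), Col1a1 for pBKSM against pOKSM (0.18, quantile normalization), Klf4 (leave-one-out -0.99 to 0.36, with 0.20 without pOKSM) and Sox1 (-3.10 to 0.0025) for polycistronic lines against mcBKSM, and Nes for DTA (-0.0695, length trend removed). Removal of the length trend was chosen after seeing the data. Depth limits values under about 0.14 FPKM, and pooled RNA limits all p-values to spread between lines.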

Other observations

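All tests in this part were chosen after the results were seen. Hox transcripts followed clusters by line: at 1 FPKM or more, pOKSM had 18 of 39 Hox genes and the mcBKSM clones 16 and 17, with 5 Hoxb and 6 Hoxd genes in each of the 3, and none from the Hoxc cluster. Hoxd13, the most posterior gene of its cluster, was 15.5 FPKM in pOKSM, 11.5 and 18.6 in the clones and listed at 0 in cNSC. MEF had 11 and DTA 26, with 6 Hoxc genes in DTA. Cdkn2a, a cell cycle inhibitor locus, was 295 FPKM in pOKSM and 453 and 378 in the clones, against 97.46 in pBKSM, 53.6 in DTA, 82.4 in MEF and 20.9 in cNSC, while Cdkn1a was 274 in pBKSM, 275 in DTA, 65.3 in pOKSM and 33.0 and 9.55 in the clones. Among lists of other cell types, endothelial (12 genes), skeletal muscle (12 genes), epithelial (14 genes) and blood and microglia (14 genes) markers had mean log2(FPKM + 1) values of 0.165, 0.285, 0.0351 and 0.343 over the iNSC lines, with 0.678 for blood and microglia in DTA. Hoxd13, Cdkn2a and Cdkn1a were picked after their values were seen.

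The pOKSM library lay close to the clones labelled mcBKSM, whose label gives another vector type and factor set, though Pou3f4 was listed at 0 in both. Whether RNA of these clones is in this library cannot be told apart from a similar cell state: of 4135 genes at 20 FPKM or more in both clones only Eif3j1 and Snora65 were below 0.1 of the clone mean, and Eif3j1 shares reads with Eif3j2, the 2 copies summing to 27.6 FPKM in pOKSM and 27.8 in the clones. Genes off in both clones and on in pBKSM (41 genes) had a median of 0.208 of their pBKSM level in pOKSM (quartiles 0.119 and 0.246), but the pBKSM line as their source is argued against by 2 of 14 abundant ones, Eif2s3y and Tex13, listed at 0 where 6.48 and 6.70 FPKM would be needed. A hypothesis is that the pOKSM pool held cells in 2 states, 1 like the clones and 1 like pBKSM. Eif2s3y and Tex13, listed at 0, also count against a state just like the sequenced pBKSM line. Genes on in the clones and off in pBKSM (38 genes) kept a median of 0.691. The 2 medians sum to 0.899 (95% bootstrap interval 0.786 to 0.968), where a mixture needs about 1. The interval was drawn over genes, which are not independent, so it may be too narrow, and its upper end lies below 1. Its lower end lies below the limit of 0.8 set for the sum. A mixture therefore cannot be told apart from graded expression in all cells, and a wrong label was not tested.

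Y-linked transcripts were at or under the detection floor in MEF and DTA: Ddx3y was listed at 0 in MEF and 0.0392 FPKM in DTA, against 11.4 to 28.3 in the other lines and 16.4 in cNSC, whose labels describe female animals. Eif2s3y was on in cNSC (48.2 FPKM) and pBKSM (31.2) and listed at 0 in pOKSM and both clones, which had Ddx3y, Kdm5d and Uty. Xist was at most 0.182 FPKM in MEF and DTA, where cells with 2 X chromosomes, 1 of them inactive, would express it. It reached 1 FPKM in no library, so these data do not show that Xist could be detected, and this question stays open. Whether the MEF library and the lines came from the same embryos cannot be told apart from loss of the Y in culture, since 4 iNSC libraries had Ddx3y at 5 FPKM or more while in MEF Xist was low and Ddx3y, Kdm5d, Uty and Eif2s3y were listed at 0.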
